A study of Mus musculus with 12 samples.

How the data were processed

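Mature miRNAs were measured in mouse embryonic fibroblasts on 1-colour Agilent miRNA arrays. The 12 arrays fall into 6 groups of 2: wild-type cells and cells lacking the endoplasmic reticulum stress transducer ATF6b, each untreated or given 2 ug/mL tunicamycin for 12 h or 24 h. Per the labels, RNA was labelled with Cy3 from 100 ng of total RNA, and the 2 arrays of a group come from separate experiments.

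The authors deposited scanner tables holding spot intensity on a linear scale, extracted with Agilent Feature Extraction 10.7.1.1 per the submitters' processing notes and the file headers. The background-subtracted intensity was used here. It can be negative. Each array carries 13000 spots of 1857 probes for 650 miRNAs, of which 611 are mouse and 39 are viral, and 715 control spots, which were left out. The authors also deposited a table of log2 values. Set against the scanner files, it equals the log2 of the software's total gene signal to within 1.18e-06, is empty where a miRNA was not detected, and is not scaled between arrays. Its column medians run from 5.75 to 6.87. Array names of miRNAs were kept as the files give them. No genome coordinates are given, because the build behind the array names is not given in the sources used here.

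From the intensities, spots of a probe were averaged without those the software marked as outliers, probes of a miRNA were summed, and each array was divided by its 75th percentile over the 93 miRNAs detected on all 12 arrays. Values were then floored at 0.0191 of that percentile, a log2 value of -5.71, and log2 was taken. The floor is the median over arrays of the lowest scaled signal of a detected miRNA. The test covered 176 mouse miRNAs detected on both arrays of at least 1 group. Where a miRNA was undetected on both arrays of a group, a change is given as a bound, the brighter group's mean against, on each array of the other group, that array's lowest detected signal or the miRNA's own signal, whichever is higher. A miRNA at the floor on both arrays of a group shows no spread there, so its standard error leans on the other groups. The floored group still counts towards the residual degrees of freedom, so that error and its p-value can be too small.

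Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; 6 residual and 1.65 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 176 miRNAs and a threshold of 0.05. A miRNA past it is described as called. There were 12 comparisons: 4 of tunicamycin against untreated cells, 2 differences of that response between genotypes, 3 of knockout against wild type, 2 of 24 h against 12 h, and 1 of genotype over all conditions with condition as a term. On simulated data for the 12 h comparison in wild type, the fit called 66.1% of miRNAs changed by a log2 value of 1. It called 87.2% of those changed by 2, and 5.60% of its calls were false. The simulated values varied independently, without effects of run or slide and without a floor. The rates therefore need not hold for the data.

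Before the data were examined, 20 miRNA lists were fixed, and 14 had at least 3 tested members. They cover miRNAs reported to rise or fall in the unfolded protein response, let-7, the miR-17 clusters, the group of miR-15, miR-16, miR-322 and miR-503, the miR-34, miR-30 and miR-29 families, the miR-23, miR-27 and miR-24 clusters, fibroblast markers, the imprinted Dlk1-Dio3 clusters, the Sfmbt2 cluster, star strands, viral miRNAs and markers of epithelial, blood, muscle, neural, endothelial and liver, and pluripotent cells. Names were matched without the arm or star unless a list gave the arm, so a star strand of a listed miRNA counts as a member. Such strands are miR-24-1* and miR-24-2* among miRNAs reported to rise in the unfolded protein response, and miR-17* among those reported to fall. Lists were tested with camera at a preset correlation of 0.01. Named miRNAs were chosen by a rule fixed at the same time: up to 10 of the largest rises and of the largest falls among called miRNAs whose arrays did not overlap between groups (a condition not applied to the response differences and the all-conditions comparison), the 5 smallest unadjusted p-values where fewer than 5 were called, measured members of the unfolded protein response lists, and up to 4 members of other lists.

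All untreated arrays lie on 1 slide and all treated arrays on the other, so slide and treatment cannot be told apart. Each slide was processed in 2 runs, and a run holds both genotypes with the same replicate number. Deviations of same-numbered arrays from their group means correlated between groups at 0.48 for untreated cells and at 0.76 to 0.91 for treated cells, so replicate numbers mark the run within a slide, as the shared prefixes of the raw file names in the labels also show. Between slides the same correlation lay from -0.38 to -0.05. The fit takes these deviations as independent between groups, so its 6 residual degrees of freedom overstate the information. The p-values for tunicamycin against untreated cells can therefore be too small. A run block cannot be fitted for those comparisons, because no run holds both untreated and treated arrays. Wild-type arrays always lie in slide row 1 and knockout arrays in row 2. The number of arrays, 2 per group, limits the precision.

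Alternatives fixed beforehand were quantile normalization, the 75th percentile over all miRNAs, the software's total gene signal, the deposited log2 table, no filter, only miRNAs detected on all arrays, a floor 4 times lower, replicate and run blocks, the run as a random block (correlation 0.504), camera with an estimated correlation, fry, and leaving out each array. A group left with 1 array is then assumed to vary like the others. A block for slide or scan date was not run, because slide equals the split into treated and untreated and scan date equals run. A further 3 choices were added after seeing the data: normexp background correction with an offset of 50, detection from spots well above background, and leaving out the 3 dimmest arrays. The planned normexp setting needs a mean signal that the files lack, so median signals were used. Its first fit, on all spots, called 0 miRNAs in each of the 12 comparisons (limma, 1 to 44 at an unadjusted p under 0.05) because it failed on 1 array, wild type at 12 h replicate 1. There 20 spots carry a flagged local background reaching 103209, against 36 at most for the other spots, and the fitted level of miR-31 came out at 1163 instead of 122. That fit was discarded, and the version reported leaves out spots with a flagged background on every array.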

Results

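The arrays record mature miRNAs in mouse embryonic fibroblasts with and without ATF6b, one of the membrane-bound transcription factors that are cleaved when unfolded proteins build up in the endoplasmic reticulum. Tunicamycin blocks N-linked glycosylation and so provokes that stress. The design text asks which miRNAs answer to 12 h of tunicamycin in a manner that depends on ATF6b. Each of the 6 groups has 2 arrays. ATF6b itself is not on a miRNA array, so the genotype labels could not be checked.

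Between 114 and 191 miRNAs were detected per array. Signal was lower on 3 arrays of the second treated run: the 75th percentile was 257 for wild type at 24 h, 246 for knockout at 12 h and 208 for knockout at 24 h, all replicate 2, against 412 to 623 on the other arrays. miR-21, abundant in fibroblasts, took 23.3% to 28.5% of the summed signal. The fibroblast list had 10 to 15 of its 22 array members detected on each array. The neural list and the endothelial and liver list had 0 members detected on any array. Tested on the deposited log2 values, which are not scaled between arrays, 0 miRNAs were called in each of the 12 comparisons (limma variance shrinkage, 1 to 28 at an unadjusted p under 0.05), so the calls given here rest on the scaled probe sums.

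Wild-type cells given tunicamycin for 12 h lost miR-31, which was detected on both untreated arrays and on neither treated one. Its level was at least 13.0-fold lower (fitted log2 change -4.10 ± 0.20 SE, limma adjusted p = 8.45e-06, n = 2 per group). The opposite strand, miR-31*, was at least 3.56-fold lower and was likewise undetected after treatment. miR-143, a smooth muscle and fibroblast miRNA, fell by 1.89 and miR-23b by 1.79 on the log2 scale. Among called miRNAs whose arrays did not overlap between groups, the largest rises were those of miR-7a at 1.94 ± 0.15, miR-92a at 1.80 ± 0.13 and miR-148a at 1.74 ± 0.17. However, miR-7a and miR-148a turned lower when the scanner software's total signal took the place of the probe sums. That signal exceeds the sum of the software's own probe totals for many dim miRNAs.

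Members of the miR-17 clusters, which promote proliferation, rose together at 12 h in wild type: 9 of 10 tested were called and the median log2 change was 1.37 (also 9 adjusted over the list alone). The list's camera adjusted p was 6.01e-07, and with an estimated correlation its adjusted p = 0.46. All 4 tested members of the cell cycle linked group of miR-15, miR-16, miR-322 and miR-503 rose, among them miR-322 by 1.62 and miR-15b by 1.60 (camera adjusted p = 0.000547, adjusted p = 0.45 with an estimated correlation). Of the fibroblast markers 10 of 15 tested fell (also 10 adjusted over the list alone), among them miR-31, miR-143 and miR-214, with a median log2 change of -0.82 (camera adjusted p = 0.000547, adjusted p = 0.61 with an estimated correlation). The 1 tested muscle marker, miR-206, was called higher by 1.33 ± 0.41 (adjusted p = 0.037), but not with quantile normalization, scaling over all miRNAs, normexp or the software's total signal. In the imprinted Dlk1-Dio3 clusters 16 of 32 tested members fell and 0 rose (also 16 adjusted over the list alone), with miR-433 at -1.81, miR-431 at -1.74 and miR-410 at -1.65 (camera adjusted p = 1.39e-05, adjusted p = 0.50 with an estimated correlation). Among listed miRNAs reported to rise in the unfolded protein response 0 of 8 rose and 5 fell, including miR-199a-5p at -1.01 and miR-214 at -0.87 (camera adjusted p = 0.154). Another of the 5, miR-24-2*, is listed only by name matching and turned higher with the deposited values. That list has 18 entries on the array, and only those 8 passed the detection filter. The response of its other entries was not tested. Among listed miRNAs reported to fall 5 of 10 tested rose, including miR-106b at 1.42 and miR-25 at 1.31. In the same list miR-34a fell by 0.86 (camera adjusted p = 0.0867). Of these 5, miR-25 and miR-96 reversed with the software's total signal, to -0.071 and -3.02, and miR-96 also with the deposited values. In all, 67 of 176 miRNAs were called, 25 higher and 42 lower. That number was 38 without wild type untreated replicate 1 and 43 without wild type 12 h replicate 2, and 3 when arrays were scaled over all miRNAs, a setting under which miR-31 stayed called and miR-92a did not. Untreated and treated arrays lie on different slides, so slide and treatment cannot be told apart.

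**Figure D1:**
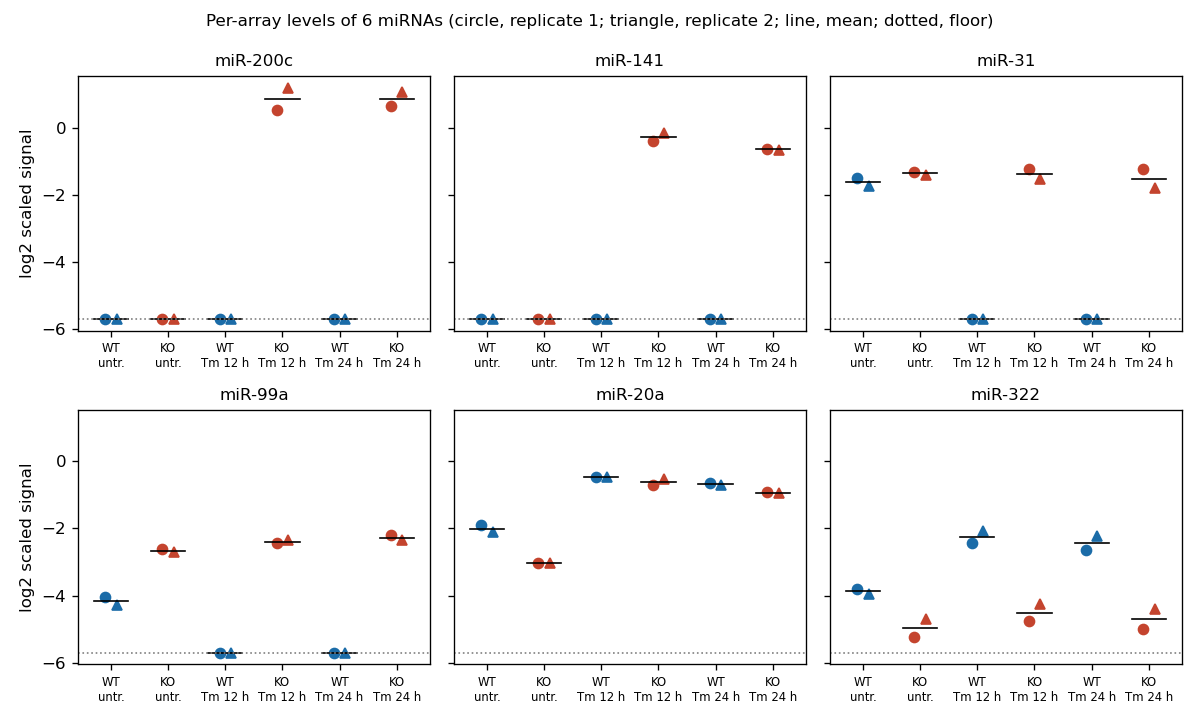
Log2 scaled signal of 6 miRNAs on each of the 12 arrays, by group (untr., untreated; Tm, tunicamycin; WT, wild type, blue; KO, knockout, red), with replicate 1 as circles, replicate 2 as triangles, group means as lines and the floor of -5.71 dotted. miR-200c and miR-141 leave the floor only on the 4 treated knockout arrays, and of the 12 arrays miR-31 lies at the floor on the 4 treated wild-type ones.

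After 24 h in wild type miR-31 was again undetected, at least 11.4-fold lower than in untreated cells. miR-148a stood 2.05 ± 0.17 higher on the log2 scale (adjusted p = 8.94e-05), miR-92a 1.68 ± 0.13 and miR-15b 1.49 ± 0.13, and with the software's total signal miR-148a turned lower. miR-143 fell by 2.14 and miR-410 by 1.91. Of the imprinted Dlk1-Dio3 members 23 of 32 fell, and 24 adjusted over the list alone (camera adjusted p = 5.27e-07, adjusted p = 0.45 with an estimated correlation), and 11 of 15 fibroblast markers fell (camera adjusted p = 0.000155, adjusted p = 0.53 with an estimated correlation). In total 76 miRNAs were called, 24 higher and 52 lower. The number was 50 without wild type 24 h replicate 2, and 1, a lower one, with scaling over all miRNAs.

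Knockout cells given tunicamycin for 12 h gained the epithelial miRNAs miR-200c, miR-141 and miR-200b, which repress the Zeb factors. These 3 were undetected on every untreated array. The epithelial list had a camera adjusted p = 9.51e-05 (adjusted p = 0.47 with an estimated correlation). Of its 12 entries on the array only these 3 were tested. They passed the detection filter only through the treated knockout arrays, so the list's p-value adds no support beyond the 3 themselves. miR-200c was at least 73.9-fold higher (fitted log2 change 6.57 ± 0.23 SE, limma adjusted p = 3.6e-07), miR-141 at least 33.5-fold and miR-200b at least 15.3-fold, on both arrays of the group. Each lay at the floor on every untreated and wild-type array, so the error and p-value given can be too small. miR-7a was at least 7.66-fold higher and miR-96 at least 5.18-fold. The miR-17 clusters rose here too, with 9 of 10 members called and miR-20a at 2.43 and miR-106b at 2.37 (camera adjusted p = 1.38e-05, adjusted p = 0.47 with an estimated correlation). All 4 tested miR-29 family members were called higher, although the list itself did not pass (camera adjusted p = 0.0699) and miR-29a turned lower with the deposited values. The falls were smaller: miR-30c changed by -1.16 and miR-342-3p by -1.02, and both turned higher with normexp background correction.

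Of the 176 miRNAs 45 were called at 12 h in knockout cells, 38 higher and 7 lower. With quantile normalization the split was 19 higher and 7 lower, and with scaling over all miRNAs 11 higher and 0 lower. At 24 h 54 were called, 45 higher and 9 lower, which became 32 without knockout untreated replicate 1 and 7, all higher, with scaling over all miRNAs. miR-200c was then at least 73.7-fold, miR-141 at least 26.2-fold and miR-200b at least 12.8-fold above untreated cells. miR-375, another epithelial and endocrine miRNA, was at least 3.23-fold higher and detected on 1 of the 2 arrays. Of 10 tested let-7 members 7 rose at 24 h, and 9 adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.65 with an estimated correlation).

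The response to 12 h of tunicamycin differed between genotypes for 43 miRNAs, 39 with a higher and 4 with a lower response in knockout cells. The median difference over all tested miRNAs was 0.37 on the log2 scale. It was 0.18 with quantile normalization and 0.11 with scaling over all miRNAs, so the lean towards higher responses depends in part on the scaling. Among called miRNAs the largest fitted differences were those of miR-200c (6.57), miR-141 (5.43) and miR-200b (4.30), which rose in knockout cells and stayed undetected in wild type. miR-31 followed at 4.08 (adjusted p = 2.96e-05): it was undetected in treated wild type and detected on every knockout array. The floor sets the size of these 4 differences. miR-31 lies at it in treated wild-type cells, and miR-200c, miR-141 and miR-200b lie at it in untreated knockout cells and in all wild-type cells. miR-143 differed by 2.04 and miR-96, at the floor in untreated knockout cells, by a fitted 1.99. miR-30c at -1.55, miR-218 at -1.21 (at the floor in 3 of the 4 groups), miR-15b at -0.82 and miR-16 at -0.69 had the lower response in knockout cells, and miR-30c and miR-218 turned higher with normexp.

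On the list reported to rise in the unfolded protein response, 3 of 8 tested members had a higher response in knockout cells (camera adjusted p = 0.364). They were miR-24, miR-24-1* and miR-24-2*. The star strands are on the list only by name matching. With the run as a block 61 were called. The 12 h number was 21 without wild type untreated replicate 1, 28 without knockout untreated replicate 1, 25 without knockout 12 h replicate 1, 23 without wild type 12 h replicate 2 and 24 without knockout 12 h replicate 2. It was 17 with quantile normalization, 5 with normexp and 4 with scaling over all miRNAs. miR-200c, miR-141 and miR-31 were called under each of the settings kept that gave them a value, which leaves out the discarded normexp fit on all spots.

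At 24 h 36 miRNAs differed in response, 35 of them higher in knockout cells. The number was 12 with quantile normalization, 11 of them higher, 4 with scaling over all miRNAs and 3 with normexp. Quantile normalization and scaling over all miRNAs each shifted the median difference of all tested miRNAs by -0.24 on the log2 scale. The fitted differences were 6.57 for miR-200c, 5.08 for miR-141, 4.04 for miR-200b, 3.94 for miR-31 and 1.93 for miR-99a (limma adjusted p = 0.00014). The floor sets their size. miR-31 and miR-99a lay at it on both treated wild-type arrays, and miR-200c, miR-141 and miR-200b on the untreated knockout arrays and all wild-type arrays. miR-15b differed by -0.76. With the run as a block 60 were called, and with the replicate block 59. The number was 13 without wild type untreated replicate 1, 19 without knockout untreated replicate 1, 21 without knockout 24 h replicate 1, 10 without wild type 24 h replicate 2 and 13 without knockout untreated replicate 2.

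Without treatment, knockout cells held more miR-99a than wild type (1.5 ± 0.12, limma adjusted p = 0.00036; 1.43 and 1.57 within the 2 runs), more miR-148a (1.12 ± 0.17) and more miR-155 (0.83 ± 0.11), a miRNA of immune activation, although miR-148a turned lower with the software's total signal. They held less miR-221 (-1.28 ± 0.21), and miR-224 and miR-196a, undetected in knockout cells, were at least 2.55-fold and 2.69-fold lower. The miR-17 clusters were lower as a group, with 7 of 10 members called and 9 adjusted over the list alone, among them miR-18a at -1.17 and miR-20a at -1.03 (camera adjusted p = 5.64e-07, adjusted p = 0.30 with an estimated correlation). Of 4 miR-29 family members 3 were lower (camera adjusted p = 0.00862, adjusted p = 0.30 with an estimated correlation). In total 20 were called, 3 higher and 17 lower. With the run as a block 33 were called and with the replicate block 37, and the number was 7, 10 or 12 without wild type untreated replicate 1, knockout untreated replicate 1 or knockout untreated replicate 2, and 0 with scaling over all miRNAs (limma, 14 at an unadjusted p under 0.05).

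At 12 h of tunicamycin knockout cells held at least 72-fold more miR-200c than wild type, at least 32.6-fold more miR-141 and at least 15.2-fold more miR-31. miR-99a lay at the floor on both wild-type arrays, which sets its fitted difference of 3.31 on the log2 scale (limma adjusted p = 3.19e-07). miR-23b was higher by 2.20 ± 0.19. miR-322 was at least 4.63-fold lower, and 3 of the 4 tested members of its group with miR-15, miR-16 and miR-503 were called lower (camera adjusted p = 0.00255, adjusted p = 0.32 with an estimated correlation). Of 176 miRNAs 67 were called, 52 higher and 15 lower, and 91 with the run as a block. The number was 44 without knockout 12 h replicate 1 or without replicate 2 of that group, and the split with quantile normalization was 24 higher and 13 lower.

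At 24 h the same miRNAs led: miR-200c at least 62.6-fold, miR-141 at least 22.3-fold and miR-31 at least 12.1-fold higher in knockout cells. miR-99a again lay at the floor on both wild-type arrays, which sets its fitted difference of 3.44, and it did not pass with normexp. miR-322 changed by -2.25 ± 0.30 and miR-25 by -0.93 ± 0.14, and both turned higher with the deposited values. Of the imprinted Dlk1-Dio3 members 14 of 32 were higher in knockout cells (camera adjusted p = 0.0501). There were 61 called miRNAs, 48 higher and 13 lower, and 84 with the run as a block, against a split of 19 higher and 15 lower with quantile normalization. Within each of the genotype comparisons knockout and wild type also differ in slide row, which cannot be told apart from genotype. The tests used no information on the cell lines or embryos behind each genotype. A difference between lines therefore cannot be told apart from the loss of ATF6b.

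**Figure D2:**
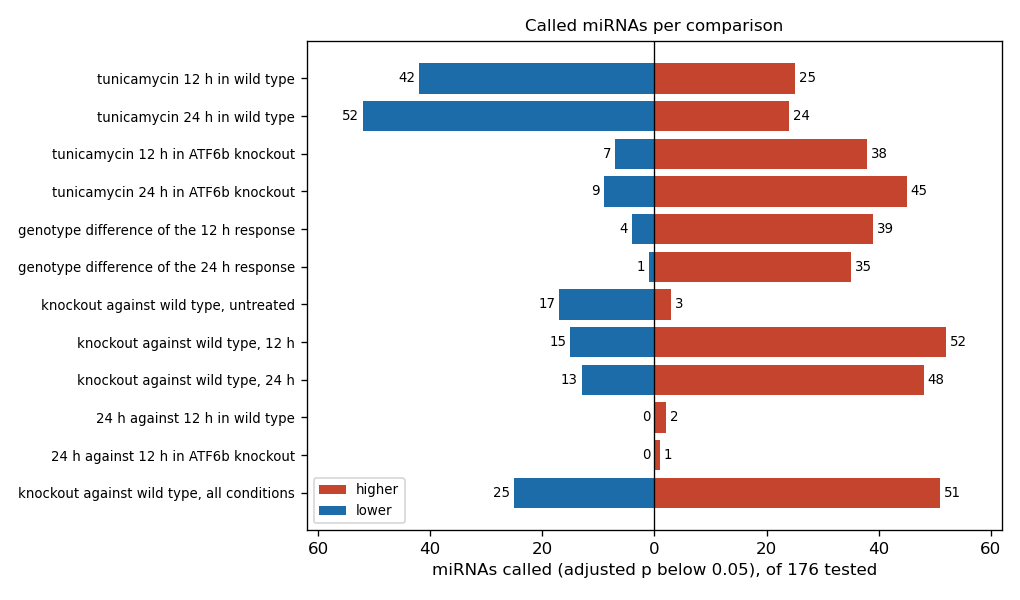
Number of called miRNAs (limma adjusted p below 0.05) of 176 tested, for each of the 12 comparisons, with higher ones in red to the right and lower ones in blue to the left. Wild-type responses hold more falls than rises, 42 against 25 at 12 h, and knockout responses more rises, 38 against 7.

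Between 12 h and 24 h of tunicamycin few miRNAs differed. In wild type miR-1224 was 1.79 ± 0.20 and miR-689 1.69 ± 0.16 higher at 24 h (1.49 and 2.09, and 1.64 and 1.75, within the 2 runs), the 2 called, of which miR-689 turned lower in the deposited values. miR-135a*, miR-7a and miR-690 had the next smallest p-values and did not pass. In knockout cells miR-689 alone was called, at 1.15 ± 0.16 (adjusted p = 0.0189), and miR-1224 at 1.03 did not pass (adjusted p = 0.0826). With the run as a block 4 were called in wild type and 3 in knockout cells, and with the replicate block 4 and 2. The knockout call was lost, leaving 0 (limma, 7 to 27 at an unadjusted p under 0.05), without either untreated knockout array, either 24 h knockout array or knockout 12 h replicate 2.

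Over all conditions 76 miRNAs differed between knockout and wild type, 51 higher and 25 lower, and 86 with the run as a block. miR-99a was higher by a fitted 2.75 (limma adjusted p = 0.000175), a size that the floor sets in part, since all 4 treated wild-type arrays lay at it. miR-152, a fibroblast marker on the list, was higher by 1.46 ± 0.23 and miR-143 by 1.78 ± 0.35. miR-224, undetected on every knockout array, at a fitted -1.46, miR-322 at -1.86 ± 0.24 and miR-221 at -0.81 ± 0.16 were lower in knockout cells, and miR-224 turned higher with normexp. The miR-17 clusters had 7 of 10 members called lower (camera adjusted p = 2.43e-05, adjusted p = 0.25 with an estimated correlation). The split was 28 higher and 27 lower with quantile normalization and 12 higher and 19 lower with scaling over all miRNAs.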

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

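The results here were picked out because the response to tunicamycin differed between the genotypes by a test of the difference itself. Of the tests of explanations below, only the count over other splits was set before its result was seen.

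At 12 h 43 miRNAs differed in response. On the fitted log2 scale they include miR-200c by 6.57, miR-141 by 5.43, miR-200b by 4.30, miR-31 by 4.08, miR-31* by 2.57, miR-375 by 2.14, miR-590-5p by 2.05, miR-143 by 2.04, miR-29b* by 2.04 and miR-96 by 1.99. The lower responses in knockout cells were miR-30c at -1.55, miR-218 at -1.21, miR-15b at -0.82 and miR-16 at -0.69. At 24 h 36 differed, including miR-200c by 6.57, miR-141 by 5.08, miR-200b by 4.04, miR-31 by 3.94, miR-375 by 2.05, miR-29b* by 2.01, miR-31* by 1.98, miR-99a by 1.93, miR-24-1* by 1.93, miR-23b by 1.93 and miR-15b at -0.76. Where a miRNA lies at the floor in any group compared, as miR-200c, miR-141, miR-200b and miR-31 do, the floor sets the size of its difference. With the deposited values miR-29b* turned lower at 12 h and at 24 h, and with normexp miR-30c and miR-218 turned higher at 12 h.

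The epithelial miRNAs miR-200c, miR-141 and miR-200b appear on all 4 treated knockout arrays and on no other. The slide and scan day of the treated arrays are argued against, because 0 of the 4 wild-type arrays on that slide, processed in the same runs, detect any of them. A row effect shared by both slides is argued against as well, because 0 untreated knockout arrays in row 2 detect them. Row 2 of the treated slide holds only the treated knockout arrays, so an effect confined to that row was not tested. Epithelial cells in the treated knockout cultures may be the source: 3 of the 7 miRNAs named in the list were detected on all 4 arrays, while miR-200a was detected on 2 of them and miR-429, miR-203 and miR-205 on 0, which leaves this open. A response to tunicamycin that ATF6b normally prevents is the other candidate explanation, and the change of miR-200c between 12 h and 24 h, -0.0035 on the log2 scale, did not pass and decides neither way.

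miR-31 was undetected on all 4 treated wild-type arrays. The slide and scan day are argued against, because 4 of 4 treated knockout arrays on that slide detect it. Row 1 of that slide holds only the treated wild-type arrays, so an effect confined to that row was not tested. Decay during treatment may account for the loss if miR-31 has a half-life of at most 3.24 h once its production stops. Treated wild-type cultures that lack the miR-31 locus are also a candidate explanation, since 0 of the 4 arrays detect either strand. The same finding follows from decay, so the 2 cannot be told apart.

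Many miRNAs were called against untreated cells and few between 24 h and 12 h, and the first kind of comparison crosses slides while the second does not. An effect of slide or scan day shared by both genotypes cancels in the difference of their 12 h responses, so as the whole cause it is argued against by the 43 miRNAs called there with the scaled probe sums, 21 to 44 when each array was left out in turn. That argument depends on the processing. The number was 17 with quantile normalization, 8 with the software's total signal, 5 with normexp, 4 with scaling over all miRNAs and 0 with the deposited values (limma's variance shrinkage, 9 at an unadjusted p under 0.05). Of these numbers only the 17 is enough to argue against such an effect by the bound set for this test. The 8, 5 and 4 decide neither way. The effect predicts 0, but the deposited values gave 0 in each of the 12 comparisons, so their 0 decides nothing. They also lack undetected values, so miR-200c, miR-141, miR-200b and miR-31 could not be tested there. As part of the cause it may act on the 23 miRNAs called in the same direction in both genotypes at 12 h, and it cannot be told apart from a shared response there, because slide and treatment coincide.

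For genotypes over all conditions, 1 of 100 splits of the 12 arrays into 6 and 6, the real one, called as many miRNAs. This argues against chance without excluding it. The other splits mix the genotypes, so a real difference adds to their spread and low counts follow. Genotype and slide row coincide, so the test cannot tell them apart. Nor can it tell genotype apart from a difference between cell lines. The real split called 76 and the highest of the others 38, in a split that keeps 10 of the 12 arrays on their real side. Among the drawn splits 16 balance every run, as the real one does, and the highest count among these was 0.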

How the results depend on the processing

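Normexp, detection from spots well above background and the omission of the 3 dimmest arrays were chosen after the data were seen; the other alternatives were set earlier. Of 5586 alternative values for 237 named results, 4344 kept direction and side of the threshold, 1148 kept direction and no longer passed, 14 newly passed and 80 reversed. For the 12 h response difference miR-200c, miR-141 and miR-31 passed in the same direction in each alternative counted here that gave them a value, which leaves out the normexp fit on all spots that was discarded. The floor 4 times lower moved no count by over 1.5 times. Signal over background limits what is seen on the 3 dimmest arrays, which detected 114 to 129 miRNAs. Where no cause is given, the cause was not tested.

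Scaling over all miRNAs gave 3 for wild type 12 h, 1 for wild type 24 h, 11 for knockout 12 h and genotypes at 12 h, 7 for knockout 24 h and genotypes at 24 h, 4 for 12 h response difference and 24 h response difference, 0 for untreated genotypes and 24 against 12 h in wild type and 24 against 12 h in knockout, 31 for genotypes over all conditions (limma, 14, 3 and 1 at an unadjusted p under 0.05 for the 3 counts of 0). That percentile lies near background: the one used was 18.0 to 46.1 times as high, with both extremes in untreated knockout cells, and the median residual SD was 0.55 against 0.184. Quantile normalization gave 47 for wild type 24 h, 26 for knockout 12 h, 22 for knockout 24 h, 17 for 12 h response difference, 12 for 24 h response difference, 11 for untreated genotypes, 37 for genotypes at 12 h, 34 for genotypes at 24 h, 1 for 24 against 12 h in wild type. It shifted the median log2 change of all tested miRNAs by -0.27 to 0.10, and scaling over all miRNAs by -0.37 to 0.01.

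The software's total signal gave 26 for wild type 12 h, 25 for wild type 24 h, 14 for knockout 12 h, 10 for knockout 24 h, 8 for 12 h response difference, 5 for 24 h response difference, 3 for untreated genotypes, 20 for genotypes at 12 h, 11 for genotypes at 24 h, 0 for 24 against 12 h in knockout (9 at an unadjusted p under 0.05), 17 for genotypes over all conditions, with a median residual SD of 0.334. The deposited table gave 0 for each of the 12 comparisons (limma's variance shrinkage, 1 to 28 at an unadjusted p under 0.05). It is not scaled between arrays and lacks undetected values, and its median residual SD was 0.587. Normexp gave 19 for wild type 12 h and knockout 12 h, 18 for wild type 24 h, 20 for knockout 24 h, 5 for 12 h response difference, 3 for 24 h response difference, 1 for untreated genotypes and 24 against 12 h in wild type, 12 for genotypes at 12 h, 7 for genotypes at 24 h, 0 for 24 against 12 h in knockout (1 at an unadjusted p under 0.05), 33 for genotypes over all conditions.

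Without a filter the counts were 44 for wild type 12 h, 24 for 12 h response difference, 19 for 24 h response difference, 12 for untreated genotypes, 5 for 24 against 12 h in knockout, 39 for genotypes over all conditions. With only the 93 miRNAs detected on all arrays, so fewer tested, they were 43 for wild type 12 h, 48 for wild type 24 h, 29 for knockout 12 h, 25 for 12 h response difference, 20 for 24 h response difference, 38 for genotypes at 12 h and genotypes at 24 h, 2 for 24 against 12 h in knockout, 49 for genotypes over all conditions. Without the 3 dimmest arrays, so with fewer samples, they were 47 for wild type 24 h, 33 for knockout 24 h, 20 for 12 h response difference, 13 for 24 h response difference, 38 for genotypes at 24 h, 0 for 24 against 12 h in wild type and 24 against 12 h in knockout (12 and 8 at an unadjusted p under 0.05), 19 for genotypes over all conditions. Detection from spots well above background gave 5 for 24 against 12 h in knockout. The replicate block gave 59 for 24 h response difference, 37 for untreated genotypes, 4 for 24 against 12 h in wild type, 2 for 24 against 12 h in knockout, the run block 60 for 24 h response difference, 33 for untreated genotypes, 4 for 24 against 12 h in wild type, 3 for 24 against 12 h in knockout, and the run as a random block 70 for 12 h response difference, 65 for 24 h response difference, 39 for untreated genotypes, 8 for 24 against 12 h in wild type, 6 for 24 against 12 h in knockout. Leaving out each array in turn gave 38 to 69 for wild type 12 h, 50 to 79 for wild type 24 h, 31 to 45 for knockout 12 h, 32 to 55 for knockout 24 h, 21 to 44 for 12 h response difference, 10 to 45 for 24 h response difference, 7 to 19 for untreated genotypes, 44 to 70 for genotypes at 12 h, 44 to 60 for genotypes at 24 h, 2 to 2 for 24 against 12 h in wild type, 0 to 1 for 24 against 12 h in knockout, 57 to 85 for genotypes over all conditions. Of 168 tests of the miRNA lists 50 passed with camera's preset correlation, 0 with an estimated correlation and 68 with fry, 32 of them shared with camera.

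Under the software's total signal 17 log2 changes reversed. For wild type 12 h these were miR-7a -2.47, miR-148a -2.60, miR-196a -1.35, miR-25 -0.071, miR-96 -3.02. For wild type 24 h these were miR-148a -1.32, miR-7a -3.0, miR-25 -0.35, miR-96 -0.97. For knockout 12 h these were miR-411* 0.35. For untreated genotypes these were miR-148a -1.24, miR-20b 0.79. For genotypes at 24 h these were miR-17* 1.17, miR-30c 0.068, miR-25 2.12. For genotypes at 12 h these were miR-25 2.21. For genotypes over all conditions these were miR-25 1.43. Under the deposited values 29 reversed. For wild type 12 h these were miR-7a -2.30, miR-148a -2.43, miR-196a -1.18, miR-24-2* 2.29, miR-96 -2.85. For wild type 24 h these were miR-148a -1.53, miR-7a -3.21, miR-24-2* 1.95, miR-25 -0.56, miR-96 -1.18. For knockout 12 h these were miR-20b -0.42, miR-30c 0.41, miR-29a -0.35. For 12 h response difference these were miR-29b* -0.24, miR-34a -0.035. For 24 h response difference these were miR-29b* -0.025. For untreated genotypes these were miR-148a -1.01, miR-20b 1.03. For genotypes at 12 h these were miR-30c 0.25, miR-350 0.96, miR-17* 0.30, miR-25 1.47, miR-34a -0.10. For genotypes at 24 h these were miR-322 0.34, miR-350 1.70, miR-17* 1.85, miR-25 1.78. For 24 against 12 h in wild type these were miR-689 -0.043. For genotypes over all conditions these were miR-25 1.15. Under normexp 34 reversed. For wild type 24 h these were miR-409-5p 0.011, miR-24-1* 0.10, miR-24-2* 0.16. For knockout 12 h these were miR-30c 0.25, miR-154* 0.46, miR-342-3p 0.14, miR-134 0.49, miR-411* 0.17, miR-369-5p 0.37. For knockout 24 h these were miR-690 0.32, miR-541 0.37, miR-411* 0.11, miR-154* 0.52, miR-134 0.61, miR-342-3p 0.27, miR-410 0.0040. For 12 h response difference these were miR-30c 0.11, miR-218 0.31. For genotypes at 12 h these were miR-149 0.15, miR-224 0.31, miR-17* 0.15, miR-690 0.12, miR-218 0.28. For genotypes at 24 h these were miR-350 0.023, miR-17* 0.16, miR-466a-3p 0.22, miR-224 0.25, miR-218 0.17. For genotypes over all conditions these were miR-224 0.11, miR-17* 0.034, miR-149 0.096, miR-196a 0.031, miR-466a-3p 0.11, miR-222 0.11.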

Other observations

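The comparison of the software's total signal with the sum of its own probe totals was chosen after the data were seen. The lists were fixed earlier.

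Among lists not described so far, 5 of 7 tested members of the miR-23, miR-27 and miR-24 clusters fell in wild type at 12 h (camera adjusted p = 0.0504), with miR-23b at -1.79. Star strands, the minor strands, fell in 6 of 21 cases there (camera adjusted p = 0.363). Of the miR-34 family 1 of 3 tested members fell and of the miR-30 family 2 of 7, each with a camera adjusted p of 0.555. The Sfmbt2 cluster, a repeat cluster of near-identical miRNAs, had 0 of 14 members called by limma with a median change of 2.36 (camera adjusted p = 0.0296, adjusted p = 0.66 with an estimated correlation).

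The blood cell list had 1 tested member, miR-155, detected on all 12 arrays, and the muscle list 1, miR-206. It was called higher in wild type at 12 h by 1.33 ± 0.41 (limma adjusted p = 0.037) and at 24 h by 1.32 ± 0.41 (adjusted p = 0.0331), the comparisons in which fibroblast markers fell. Neither call was kept with quantile normalization (adjusted p = 0.14 at 12 h and 0.0967 at 24 h), scaling over all miRNAs, normexp, the software's total signal, the deposited values, no filter or detection from spots well above background, nor without either untreated wild-type array. The 12 h call was also lost without either 12 h wild-type array or either untreated knockout array, and the 24 h call without wild type 24 h replicate 2 or the 3 dimmest arrays. Pluripotent cell markers were detected 0 to 3 at a time on single arrays and had 0 tested members. Of 39 viral miRNAs 4 were detected at all, 1 of them, mghv-miR-M1-2, on 10 arrays, untreated ones included.

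The deposited log2 table carries the software's total gene signal. It was set against the sum of the software's own probe totals, which are not the probe sums used for the calls. The total gene signal exceeds 2 times that sum for 561 of 1906 detected values, and 10 times for 188 of them. The excess touched 159 of 260 detected miRNAs and reached 520 times, while 1183 values lay within 1% of the sum. The median sum of probe totals was 14.3 where the excess occurred and 94.5 where the values matched. For miR-100 on wild type 24 h replicate 2 the total gene signal was 348 against a sum of probe totals of 26.5. For let-7d* on wild type 12 h replicate 1 it was 538 against 6.18.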
